A study of Drosophila melanogaster with 2 samples.

How the data were processed

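Protein-DNA contacts of a CG11696-eGFP fusion were measured by chromatin immunoprecipitation and sequencing in whole embryos of 0 to 24 h, in 1 group of 2 biological replicates. Per the labels, chromatin was sheared by sonication to a size range of 200 to 800 bp and precipitated with an antibody against the fluorescent tag. Each replicate had 1 list of ranked peaks and 1 of thresholded peaks, and the series had another pair of each, named conservative and optimal in the deposited descriptions. All lists were made by the authors on assembly dm6 and, per the deposited descriptions, from the alignments of the samples and of a control. The aligner, the peak caller, their versions and their settings are not given in the sources used here, nor are the read depths, so the depth is unknown. Intervals and tests cover the counting of the peaks or genes that were called, and not what another depth would have called.

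The deposited score of each peak runs from 0 to 1000. In the ranked lists it was proportional to the negative log2 of the global IDR, capped at 1000, within 1 unit for all peaks, and no thresholded list held a score under 830, which corresponds to an IDR of 0.01. The IDR itself was deposited as its −log10. It is the expected share of peaks irreproducible between a pair of peak sets, among all peaks of that rank or better, and not a p-value. The deposited signal value is the authors' measure of peak strength, in units of their peak caller, and it was not scaled between lists. How it was computed is not given in the sources used here. Tests on the values showed that the conservative ranked list carries the values of the 2 replicates beside the pooled ones. Replicate values of a conservative peak, given as mean ± SD, are the signal values of the replicate peaks matched to it there, and a peak with a value in a single replicate has no SD. The optimal ranked list carries a further pair of peak sets whose origin is not given in the sources used here.

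Some peaks that pass the threshold in a ranked list are absent from the thresholded list of the same name, 70 in replicate 1, 85 in replicate 2, 94 in the conservative and 120 in the optimal list. The thresholded lists name an additional source, which the descriptions used here do not explain. The thresholded lists also hold weak peaks beside strong ones. In the conservative list 176 peaks had a signal value below 22.7, the median of the ranked list, and 174 of them overlapped a stronger peak of the list, with which they share the IDR score.

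Coordinates are 1-based on dm6. Genes came from Ensembl release 115 and sequence from the RefSeq copy of the same Release 6 assembly, and every peak on the 7 chromosomes used (2L, 2R, 3L, 3R, 4, X and Y) ended within the length of its chromosome there. Peaks on other contigs, 11 in the conservative list, were left out of the comparisons. Each summit was assigned to a single class, in this order of priority: within 500 bp of any of 24111 annotated TSSs, 5' UTR, coding exon, 3' UTR, other exon, intron, intergenic. Sub-threshold peaks, the ranked peaks of the same list that did not pass and did not overlap a thresholded peak, served as the background of weaker sites.

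The share of peaks common to both replicates used an overlap of at least 1 bp, with 95% Wilson intervals and 1000 random draws of sub-threshold peaks. Overlap with the ranked list of the other replicate was set against 100 random placements on the same chromosomes, added after seeing the data. Classes and chromosomes were compared with two-sided exact binomial tests against bases and with two-sided Fisher's exact tests against sub-threshold peaks. Chromosomes were also compared with their shares of annotated TSSs by the same binomial test. Signal values of TSS peaks and other peaks were compared by a two-sided permutation test with 100000 resamples, and correlations by as many permutations. Gene lists and biotypes were compared with all other protein-coding genes by two-sided Fisher's exact tests. Sequence was compared between the window reaching 50 bp to either side of the summit and 1 of the equally wide windows centred 300 bp to either side, drawn at random per peak, with the two-sided exact McNemar test. 8-mers on both strands were merged and tested where they occurred in at least 10 windows. Each family of tests (7 classes, 7 chromosomes, 22 gene lists, 6 biotypes, 16 consensus sequences, all 8-mers) was adjusted by the Benjamini-Hochberg method, and the threshold was 0.05.

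The tests, the gene lists, the consensus sequences and the rule for named genes were fixed before the data were examined. Genes named were CG11696, the gene with the TSS nearest to each of the 20 conservative peaks of highest signal value (a protein-coding gene first where TSSs tied), and up to 4 bound members of each list with the highest promoter peaks. The 5 further bound members of the signalling list, the PGRP-SA peak, the snRNA gene and the genes and sequences in the closing section were named after their values were seen. Of the symbols in the lists, h was matched to hry and yan to aop through synonyms, while calypso, nos, Dl and rye were not matched to the annotation and left out.

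Settings varied by choices made before the data were examined were the optimal list, the stronger 50% of peaks by signal value, each replicate's own list, TSS windows of 250 and 1000 bp, other overlap rules, flanks 1000 bp away, a central window of 51 bp, a divergent distance of 500 bp, 10000 circular shifts of the bound genes along gene order, and genes with any ranked peak as background. Added after seeing the data were merging overlapping peaks, adding back the peaks absent from the thresholded lists, and random lists matched on the number of TSSs per gene. Matrices in the closing section were 32 positions wide and were fitted to all peaks of a set of chromosomes, then to its 300 strongest. Those started by hand were 23 wide and fitted to the 300 strongest alone, and a window was counted above the score of the top 1% of flanks.

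Scripts ran in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. The gene-list test was tested on simulated data over 13968 genes. Of 100 lists bound at a rate of 40% against 10%, 99.0% were called, as were 3 of 100 unchanged lists. Recovery was not measured by list size. It therefore does not carry over to short lists, such as the 8 Hox or 15 heat shock protein genes. A short list that did not pass may still differ from other genes. The 8-mer test was tested on 23838 8-mers from windows away from summits with 4 planted 8-mers, each in 3% of centres: 100.0% were recovered, with 3 calls among 8-mers unrelated to them. No shift in A/T content between centres and flanks was simulated, so this count of false calls does not cover the shift seen at summits.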

Results

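Chromatin immunoprecipitation followed by sequencing was used to map where CG11696, a predicted zinc finger protein of *Drosophila melanogaster*, sits on the genome. The flies carried a transgene for CG11696 fused to enhanced green fluorescent protein, and the fusion was pulled down with an antibody against the fluorescent tag. Chromatin came from whole embryos collected between 0 and 24 h of development. The series held 1 group with 2 biological replicates, so no contrast between conditions was possible, and the comparisons were between the replicates, between peaks and the rest of the genome, and between groups of genes. The files were lists of peaks ordered by their irreproducible discovery rate (IDR), and the read depth behind them is unknown.

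Replicate 1 had 2081 peaks that passed the authors' IDR threshold and replicate 2 had 2233. The conservative list, in which the peaks of the pooled reads were ranked by how they held up across the 2 replicates, had 3154 peaks, and the optimal list had 3752. Of the conservative peaks, 3143 lay on chromosomes 2L, 2R, 3L, 3R, 4, X or Y, and these were used below. Their median width was 344 bp and their median signal value was 107, against a median of 22.7 over all 96052 ranked peaks of the same list. The signal value is the authors' measure of peak strength, and it was used only within a list or between the matched replicate values. Pooled and replicate values are on different scales. At the highest peak the pooled value was 2101, against 1087 in replicate 1 and 976 in replicate 2. Tests over peaks or genes describe these 2 replicates, since neighbouring peaks and genes are not independent replicates.

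The 20 strongest peaks lay next to genes of mixed known functions, and all but those at chif, Dok and Raf were within 500 bp of a TSS. The highest of all was at 3R 8669147 to 8669627, 179 bp from the start of the tyrosine tRNA gene tRNA:Tyr-GTA-1-8 and within the genes CG8036 and p, with a signal value of 1031 ± 78.1 (SD, n = 2 replicates). It was followed by a peak 380 bp from the transcription start site (TSS) of CG5953 (2L 16532984 to 16533605, 963 ± 78.1, n = 2). The next was in an intron of chif, the fly orthologue of the replication kinase subunit Dbf4 (2L 16351012 to 16351430, 911 ± 22, n = 2). Of the 20 strongest peaks, those beside Eogt, which adds N-acetylglucosamine to EGF domains (693 ± 53.9), Lpin, a phosphatidate phosphatase (647 ± 39.1), Ugalt, a UDP-galactose transporter (666 ± 29.6), and Gp93, an endoplasmic reticulum chaperone (595 ± 88.8), were among them. So were those at sgg, the fly glycogen synthase kinase of the Wnt pathway (529 ± 21), shep, an RNA-binding protein (551 ± 60.6), and Trs20, a vesicle tethering subunit (549 ± 12.3). Raf, a kinase of the MAP kinase cascade, had its peak in an intron 5214 bp from the nearest TSS (539.6 ± 89.4). The remaining peaks of the 20 lay nearest to CBP, fok, Dok, POSH, CG33116, CG10165, CG4709, scramb2 and CG14100, with mean signal values from 539 at CG14100 to 830.3 at CBP.

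To see how far the replicates shared these sites, the thresholded lists of both were overlapped. Of the 2078 peaks of replicate 1, 1569 overlapped a peak of replicate 2 by at least 1 bp (75.5%, 95% Wilson interval 73.6 to 77.3). In the other direction, 1566 of 2191 peaks overlapped (71.5%, 69.5 to 73.3). Random draws of as many sub-threshold peaks gave 1.3% and 0.442% on average. These draws leave out peaks that overlap a thresholded peak of the same replicate, and so most places that both lists share. The baseline is therefore low in part by construction. Peaks seen in a single thresholded list often overlapped a ranked peak of the other replicate: 471 of 509 for replicate 1 (92.5%) and 580 of 625 for replicate 2 (92.8%). The ranked lists are long, and chance overlap is high: peaks of the same widths at random places gave 46.6% and 21.3%, and sub-threshold peaks of the same replicate 71.3% and 31.3%. With 50% reciprocal overlap the shares were 64.2% and 66.3%, against 56.0% and 22.3% of sub-threshold peaks, so for replicate 1 little of this overlap is specific to its thresholded peaks. Peaks of replicate 2 alone were less often within 500 bp of a TSS than its shared peaks (36.2% against 42.8%, two-sided Fisher's exact p = 0.00451), while those of replicate 1 were not distinguishable from its shared peaks (42.8% against 43.3%, p = 0.877). Across the 1569 shared peaks the signal values of the replicates correlated, with Spearman's rho of 0.82 and Pearson's r of 0.85 on the log2 scale (permutation p = 1e-05 for each, the smallest the permutations can give). The correlation is across peaks, which are not independent replicates. The median log2 ratio of replicate 2 to replicate 1 was 0.09, with an SD of 0.49 over peaks.

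**Figure D1:**
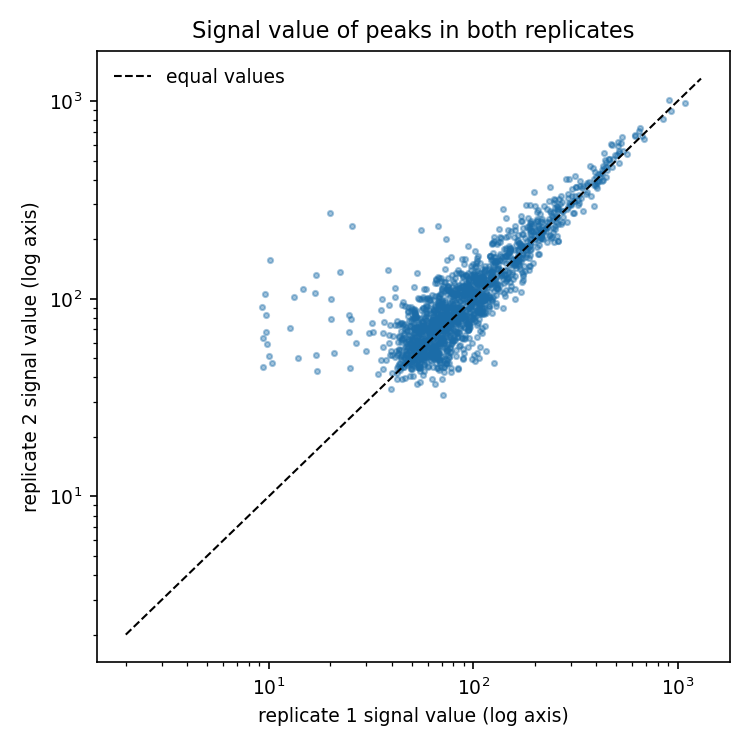
Signal value of each of the 1569 peaks found in both thresholded lists, replicate 1 on the x axis and replicate 2 on the y axis, both logarithmic; the dashed line marks equal values. Points follow the line, with Spearman's rho of 0.82.

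The conservative and optimal lists shared most of their peaks. Of the conservative peaks, 2926 (93.1%, 92.2 to 93.9) overlapped an optimal peak, and 2880 of 3727 optimal peaks (77.3%, 75.9 to 78.6) overlapped a conservative one. The 847 optimal peaks outside the conservative list were weaker, with a median signal value of 65.4 against 113 for the shared ones. Their share within 500 bp of a TSS did not differ detectably (38.1% against 41.2%, Fisher's exact p = 0.111).

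The genomic positions of the peaks were set against the annotated genes. Promoters and introns held most of the summits: 1293 of 3143 lay within 500 bp of an annotated TSS (41.1%, 39.4 to 42.9) and 1312 in introns (41.7%, 40 to 43.5). TSS windows cover 13.3% of the bases and held 16.4% of the 91996 sub-threshold peaks, so summits were 2.51 times as frequent there as among weaker peaks (Fisher's exact adjusted p = 1.7e-226). Coding exons were nearly empty, with 23 summits (0.732%, and 1.18% with the optimal list) against 17.1% of sub-threshold peaks (Fisher's exact adjusted p = 1.0e-209). Summits were also less frequent in 3' UTRs (1.11% against 3.2%, Fisher's exact adjusted p = 1.4e-13) and between genes (13.4% against 22.2%, adjusted p = 1.5e-34). Introns differed little from sub-threshold peaks (41.7% against 39.3%, Fisher's exact adjusted p = 0.00707), the call was lost with the stronger 50% of peaks (adjusted p = 0.0591), and with a TSS window of 1000 bp the intron share was the lower one. The shares of 5' UTRs (0.859%) and other exons (1.02%) did not differ detectably from those of sub-threshold peaks (Fisher's exact adjusted p = 0.521 and 0.448), though 5' UTRs were lower with a TSS window of 1000 bp (adjusted p = 0.0041). Each replicate's own list gave 43.2% and 40.9% of summits near a TSS and 0.626% and 0.867% in coding exons.

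**Figure D2:**
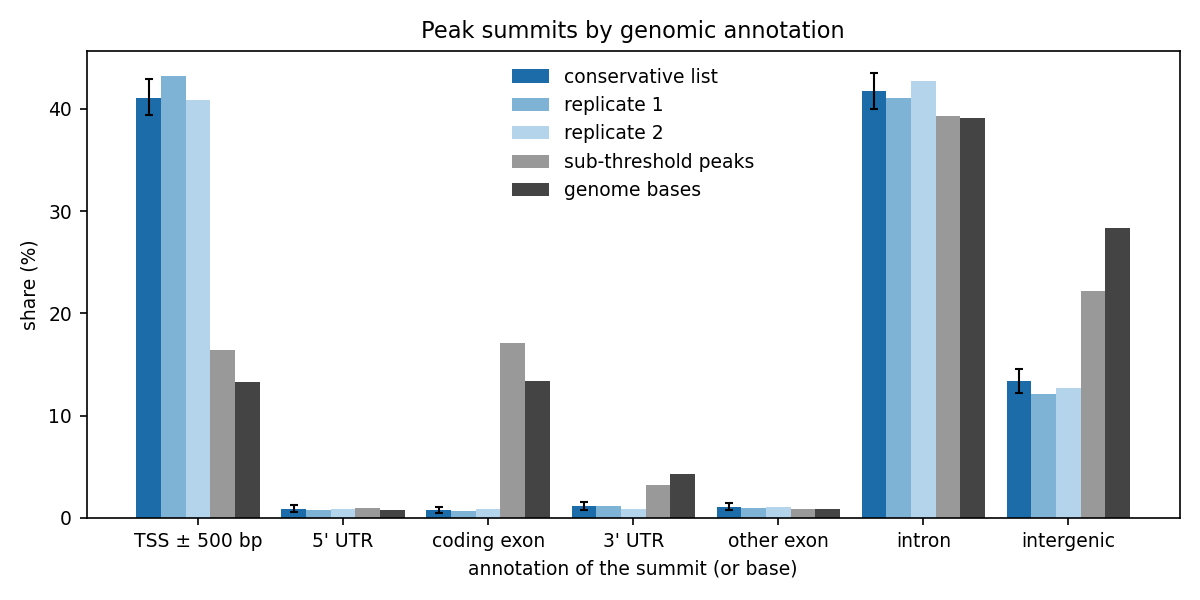
Share of summits (%, y axis) in each annotation class (x axis) for the conservative list and the lists of replicates 1 and 2, beside sub-threshold peaks of the conservative list and all bases; error bars are 95% Wilson intervals of the conservative list. The TSS class holds 41.1% of conservative summits and 16.4% of sub-threshold ones, and coding exons hold 0.732% and 17.1%.

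The X chromosome carried more peaks than its share of weaker peaks, and 3R and 2R fewer. The X held 621 peaks (19.8%), 1.19 times its share of sub-threshold peaks (16.6%, Fisher's exact adjusted p = 4.8e-05) and 1.15 times its share of bases (binomial adjusted p = 2.6e-04). Chromosome arm 3R held 689 peaks, 0.873 times its sub-threshold share (Fisher's exact adjusted p = 1.4e-04), and 2R held 513, 0.894 times its share (adjusted p = 0.0129). The call for 2R was lost with the optimal list (Fisher's exact adjusted p = 0.0808). Of the 84 peaks that pass the threshold but are absent from the thresholded list, 54 lay on 3R. With these added back, a setting added after seeing the data, 3R was at 0.917 times its sub-threshold share (Fisher's exact adjusted p = 0.0158). Against its share of bases 2L was also higher (1.14 times, exact binomial adjusted p = 0.00103), as was 3L (1.09 times, adjusted p = 0.012), while 2R was lower (0.888 times, adjusted p = 0.00385) and 3R did not differ detectably (0.94 times, adjusted p = 0.0635). Against its share of annotated TSSs 2L was no longer higher (1.0 times, exact binomial adjusted p = 0.928). Arm 2R was lower (0.791 times, exact binomial adjusted p = 6.8e-09). The X (1.21 times, exact binomial adjusted p = 1.6e-06) and 3L (1.17 times, exact binomial adjusted p = 1.7e-05) were higher. Arm 3R did not differ detectably (0.944 times, exact binomial adjusted p = 0.0972). With the optimal list 3L was also above its sub-threshold share (1.11 times, Fisher's exact adjusted p = 0.00158). Chromosome 4 had 8 peaks and Y none, and neither differed from its sub-threshold share of 0.274% and 0.0391% (Fisher's exact adjusted p = 1.0 and 0.738). Against bases both were lower, chromosome 4 at 0.26 times its share (exact binomial adjusted p = 6.7e-06) and Y with 0 peaks (adjusted p = 1.5e-36). Chromosome 4 was at 0.332 times its share of annotated TSSs. With the optimal list Y was also below its sub-threshold share (Fisher's exact adjusted p = 6.5e-05).

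Peaks near a TSS were slightly stronger than other peaks. Their median signal value was 111, against 105 for the other 1850 peaks, a difference of 0.08 on the log2 scale (two-sided permutation p = 0.0143). With a TSS window of 250 bp the difference was 0.05 and no longer passed the threshold (permutation p = 0.191). It was larger with a window of 1000 bp (0.13, permutation p = 1.2e-04) and in replicate 2's own list (0.14, p = 9.0e-04), against 0.09 in replicate 1's (p = 0.014).

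To ask which genes had a peak at their promoter, protein-coding genes were called bound where a conservative summit lay within 500 bp of any of their TSSs. Of 13968 genes, 1404 were bound (10.1%). Genes for the proteins of the cytosolic ribosome stood out: 44 of 92 were bound (47.8%, 37.9 to 57.9), 4.88 times the share of other genes (Fisher's exact adjusted p = 4.5e-19 over 22 lists). They comprised 29 of 54 large-subunit and 15 of 38 small-subunit genes. The highest promoter peaks among them were at RpL34b, RpS27, RpL32 and RpL7, with pooled signal values of 252, 211, 203 and 197. Their replicate means were 132 ± 8.79 (n = 2), 106 ± 1.75, 106 ± 9.57 and 99.4 ± 8.01. The median pooled signal value at the 44 genes was 117, near the 111 of all TSS peaks. Replicate 1's own list bound 35 of the 92 genes and replicate 2's 28, with 24 in both. Shifting the bound genes along gene order left the list above chance (permutation adjusted p = 0.00147).

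Other gene groups of the translation and energy machinery did not pass the threshold. Mitochondrial ribosomal protein genes had 12 of 73 members bound (16.4%, Fisher's exact adjusted p = 0.189), some by strong peaks, as at mRpL41 (494 ± 19.8), mRpS10 (469 ± 31.7), mRpS23 (417 ± 31.6) and mRpL23 (299.8 ± 43.6). Oxidative phosphorylation genes had 7 of 84 bound (8.33%, Fisher's exact adjusted p = 0.929), led by the complex I subunit genes ND-ASHI (353 ± 28.7), ND-PDSW (84.6 ± 5.5), ND-24 (51.5 ± 24.2) and ND-MWFE (49.7 ± 5.44). Of the proteasome genes 1 of 48 was bound, Rpn3 (76.2 ± 24.4, Fisher's exact adjusted p = 0.19). Basal transcription and Mediator genes had 10 of 63 bound (15.9%, Fisher's exact adjusted p = 0.275), with Taf5 (93.5 ± 18.7), MED27 (78.6 ± 0.365), MED30 (74.0 ± 14.9) and TfIIA-L (73.6 ± 23.3) highest.

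Genes of the Notch, Wnt, Hedgehog and EGFR pathways formed the other list above the rest of the genes, with 9 of 30 bound (30.0%, 16.7 to 47.9, ratio 3.0, Fisher's exact adjusted p = 0.0091). They were sgg, the Wnt antagonist nkd (100.3 ± 9.25), the EGFR ligand spi (63.6 ± 18.0), the EGFR antagonist aos (62.2 ± 9.95), and mam, N, Egfr, pnt and ptc with pooled signal values from 72.7 at mam to 90.0 at pnt. The call was lost in either replicate's own list, with 4 genes bound in replicate 2 (Fisher's exact adjusted p = 0.555) and 5 in replicate 1 (adjusted p = 0.166). It did not pass with the stronger 50% of peaks (ratio 2.27, Fisher's exact adjusted p = 0.267), with a TSS window of 250 bp (adjusted p = 0.227) or among genes with a ranked peak (adjusted p = 0.0503). It was also lost against lists with as many TSSs per gene (permutation adjusted p = 0.0887), a comparison added after seeing the data.

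Genes of chromatin regulators and heat shock proteins had higher shares that did not pass the correction. Insulator and architectural protein genes had 5 of 19 bound (26.3%, Fisher's exact adjusted p = 0.131), among them the chromodomain protein gene Chro (275 ± 4.44), Cp190 (86.4 ± 4.27), Trl, which encodes GAGA factor (79.2 ± 5.45), and BEAF-32 (41.2 ± 14.2). Polycomb and trithorax genes had 5 of 22 bound (22.7%, Fisher's exact adjusted p = 0.174), with ph-p (214 ± 0.679), the remodeller ATPase gene brm (189.7 ± 8.29) and the histone methyltransferase gene E(z) (84.2 ± 19.1) above Trl. Of 15 heat shock protein genes 4 were bound, Hsp27 (179 ± 7.97), Hsp83 (89.1 ± 22.2), Hsp26 (67 ± 13.8) and Hsp22 (59.8 ± 1.35, Fisher's exact adjusted p = 0.174 for the list). With the stronger 50% of peaks the heat shock list did pass (ratio 4.55, Fisher's exact adjusted p = 0.0423). A fixed selection of 20 genes from the zinc finger family to which CG11696 belongs had 2 bound. They were prg (43.9 ± 11.2) and pita, whose peak had a value in replicate 2 alone (41.6, Fisher's exact adjusted p = 1.0 for the list).

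Genes that pattern the embryo or mark its tissues did not differ detectably from other genes, with Fisher's exact adjusted p from 0.765 to 1.0 over these lists. Segmentation genes had 2 of 22 bound, the maternal determinant gene bcd (45.4 ± 9.1) and the pair-rule gene hry (43.1 ± 0.514). Among the 8 Hox genes Antp was bound (200.3 ± 79.1), and among 15 dorsoventral genes dl (39.1 ± 8.47). The proneural and neuroblast list had numb (109 ± 11.9), the neuronal list elav (156 ± 11.6), and the haemocyte and fat body list ush (60.7 ± 15.5). Muscle genes had 3 of 18 bound, the cardiac determinant gene tin (106 ± 18.9), the titin gene sls (64.1 ± 3.15) and the actin gene Act87E (35.4 ± 3.18). Cell cycle and replication genes had 2 of 34 bound, Dp (84.0 ± 14.1) and Cdk1 (44.2 ± 21.4, Fisher's exact adjusted p = 0.903 for the list). None of 11 testis-specific meiotic arrest genes was bound (upper 95% bound 25.9%, Fisher's exact adjusted p = 0.904).

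Genes of late or sensory functions lay below the rest. None of 179 chemosensory receptor genes (upper 95% bound 2.1%, Fisher's exact adjusted p = 1.1e-07) and none of 117 cuticle protein genes (upper bound 3.18%, adjusted p = 5.3e-05) had a conservative promoter peak. The replication-dependent histone genes had 0 of 111 bound (Fisher's exact adjusted p = 9.8e-05), but they are near-identical repeats and 5 of them had any ranked peak. Peaks that pass the IDR threshold but are absent from the thresholded list lay 750 and 626 bp from histone gene TSSs. Their pooled signal values were 118 and 90.2, and both were outside the 500 bp window. Among genes with a ranked peak at the TSS, the histone list could not be told from other genes (Fisher's exact adjusted p = 1.0).

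**Figure D3:**
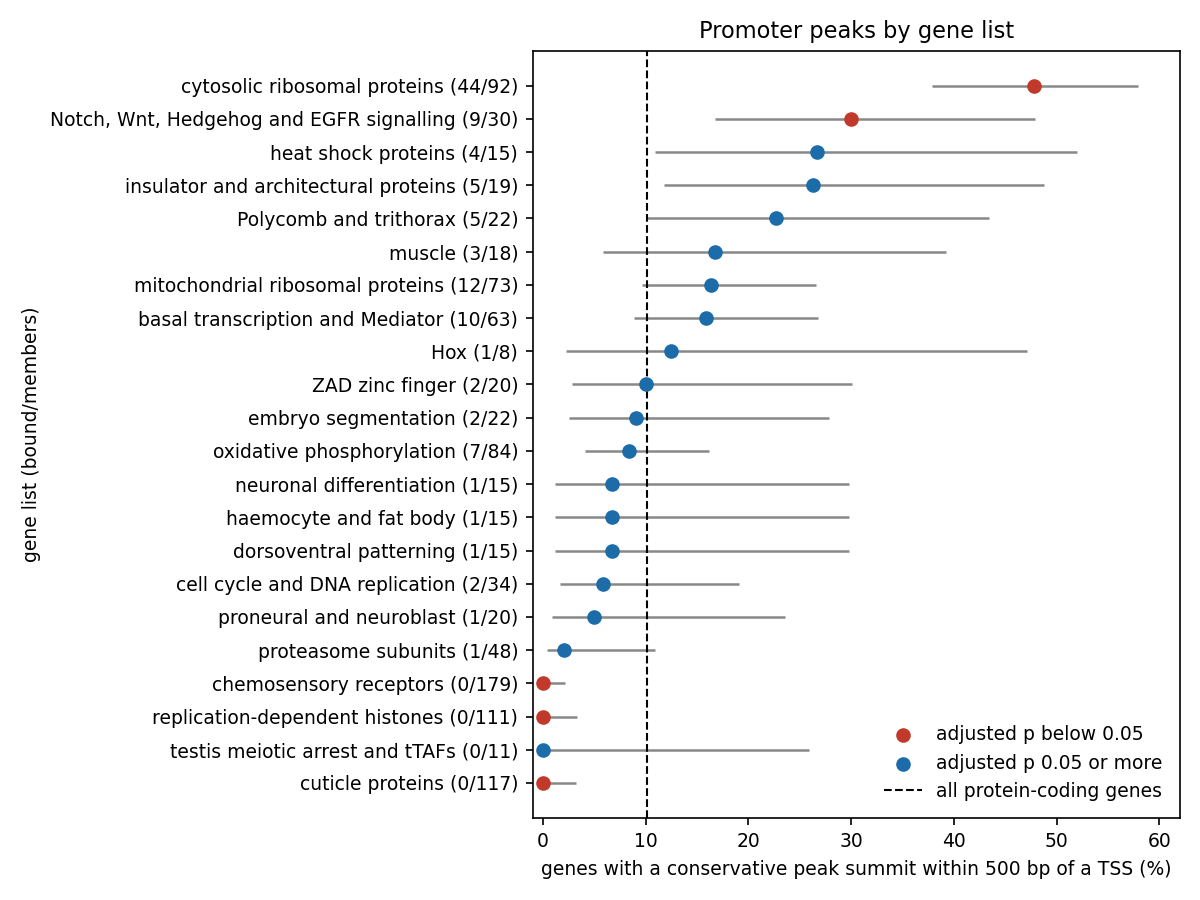
Share of genes in each list with a conservative summit within 500 bp of a TSS (%, x axis), with 95% Wilson intervals and the bound and total members after each list name (y axis); red points have an adjusted p below 0.05 and the dashed line is the 10.1% of all protein-coding genes. Cytosolic ribosomal protein genes lie highest, at 47.8%.

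Genes for small and noncoding RNAs were bound less often than protein-coding genes, whatever the strength of the single tRNA-linked peak above. Promoter peaks were found at 8 of 290 tRNA genes (2.76%, Fisher's exact adjusted p = 7.2e-06), 10 of 269 snoRNA genes (3.72%, adjusted p = 2.2e-04), 135 of 3289 other noncoding RNA genes (4.1%, adjusted p = 1.5e-30), 3 of 330 pseudogenes (0.909%, adjusted p = 4.7e-11) and 0 of 99 rRNA genes (upper 95% bound 3.74%, adjusted p = 8.8e-05). Of 32 snRNA genes 1 was bound, snRNA:U2:34ABb (Fisher's exact adjusted p = 0.368), and with the optimal list none was (adjusted p = 0.046). The tRNA share was 5.52% with the optimal list (Fisher's exact adjusted p = 6.6e-04), 7.24% with a TSS window of 1000 bp (adjusted p = 0.00777) and 1.03% with the stronger 50% of peaks (adjusted p = 1.2e-04), below other genes in each. All 8 bound tRNA genes shared their peak with a protein-coding TSS. For snoRNA genes the direction turned with a TSS window of 1000 bp (ratio 1.03), and the call was lost with the stronger 50% of peaks (ratio 0.506, Fisher's exact adjusted p = 0.0566). The rRNA and tRNA genes are multicopy, and how reads were assigned among the copies is not given in the sources used here.

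Bound TSSs were more often part of a divergent pair. Of 1792 bound protein-coding TSSs, 930 had a TSS on the other strand within 1000 bp upstream (51.9%), against 29.5% of 17838 unbound ones (odds ratio 2.58, Fisher's exact p = 5.4e-79). A summit between paired TSSs marks both as bound, which raises this share.

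At the CG11696 gene itself (X 11573731 to 11576152, plus strand), none of the thresholded lists of the replicates or the conservative list had a peak inside the gene. Its strongest ranked peak in the conservative list was at X 11573996 to 11574339, 437 bp from the TSS, with a pooled signal value of 70 and an IDR score of 640, under the threshold of 830. Within 20 kb on either side there were 5 conservative peaks, 4 thresholded peaks in replicate 1 and 3 in replicate 2. The strongest of them lay at X 11560267 to 11560610, 1204 bp from the TSS of the immune receptor gene PGRP-SA, with a pooled signal value of 162.

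Summits were rich in A and T. The windows reaching 50 bp to either side of the summit held 64.5% A/T (SD 9.9 over 3143 windows), against 56.8% (SD 9.92) in flanking windows of the same size 300 bp away, and the centre was the richer of the pair at 2211 peaks and the poorer at 881 (exact sign test p = 2.2e-130). Sub-threshold peaks showed no such rise, as the plot of A/T content around summits shows. Of 21318 8-mers tested, 381 were more frequent in centres and 116 less frequent (exact McNemar test, Benjamini-Hochberg adjusted p below 0.05). The leading 8-mer was TATTTTAA, in 181 centres and 55 flanks (exact McNemar adjusted p = 5.4e-13), and 114 of the 381 had no G or C. Among 66 with at least 2 G or C bases, AATAGCAC led (56 centres and 12 flanks, adjusted p = 2.4e-05), followed by ATAATAGC (51 and 10, adjusted p = 3.4e-05) and AAATAGCA (64 and 17, adjusted p = 4.3e-05).

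**Figure D4:**
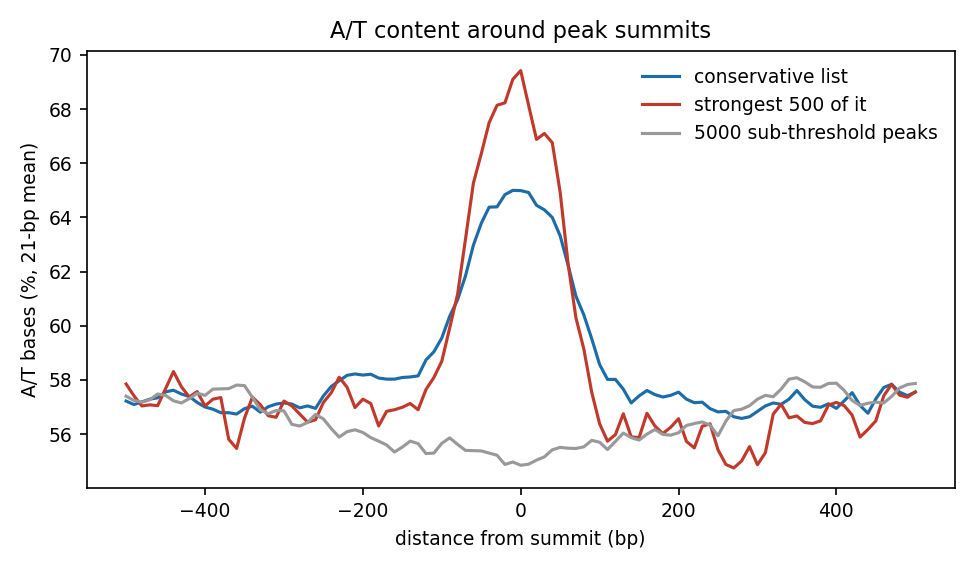
Share of A and T bases (%, y axis, running mean) by distance from the summit (bp, x axis) for the 3143 conservative peaks, the 500 strongest of them and 5000 sub-threshold peaks. At the summit the values are 64.99%, 69.42% and 54.85%.

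Of 16 known consensus sequences, the GATA factor site and a homeodomain site were more frequent in centres than in flanks. Centres hold more A and T than flanks (64.5% against 56.8%), and base composition was not matched. Both raised sites are rich in A and T, and the lowered CTCF core and E-box CACGTG in G and C. The test therefore cannot tell a gain or loss of factor sites from the A/T content of summits. GATA sites (WGATAR) were in 21.5% of centres and 15.9% of flanks (exact McNemar adjusted p = 1.2e-07), and TTAATTA was in 5.31% and 3.18% (adjusted p = 2.4e-04). The homeodomain call was lost with flanks 1000 bp away (exact McNemar adjusted p = 0.0722), with the optimal list (adjusted p = 0.107) and in replicate 2's own list (adjusted p = 0.179). Less frequent in centres were the CTCF core (2.16% against 3.98%, exact McNemar adjusted p = 2.4e-04), the E-box CACGTG (0.605% against 1.62%, adjusted p = 4.2e-04), the CA repeat (2.2% against 3.88%, adjusted p = 4.2e-04), the GAGA factor repeat (1.94% against 3.09%, adjusted p = 0.0139) and the Pho site (3.44% against 4.68%, adjusted p = 0.0334). With flanks 1000 bp away only the CTCF core of these 5 still passed. The Pho call was lost under each of its 8 alternatives (exact McNemar adjusted p from 0.0609 to 0.92). The GAGA repeat did not pass with the optimal list (exact McNemar adjusted p = 0.0534) or in replicate 1's own list (0.149), nor did the E-box CACGTG in replicate 1's own list (0.186). The sites of Zelda, DREF, BEAF-32, M1BP and Su(Hw), Ohler motif 6, the TATA box, the E-box CAGCTG and the Su(H) site did not differ detectably between centres and flanks, with exact McNemar adjusted p from 0.163 to 1.0. With the optimal list the Zelda site was less frequent in centres (0.349% against 0.885%, exact McNemar adjusted p = 0.0145).

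Peaks lay close to one another more often than weaker peaks did. Within 1 kb of another conservative summit lay 862 of the 3143 (27.4%), against a mean of 5.69% in random draws of sub-threshold peaks, and within 10 kb 2070 (65.9% against 42.7%, permutation p = 0.002 for both, the smallest possible). The draws were not matched on annotation class, and 41.1% of the conservative summits lay within 500 bp of a TSS, against 16.4% of sub-threshold ones. The comparison therefore cannot tell closeness of peaks from their placement at TSSs. The list also holds weak peaks that overlap a stronger one and share its IDR score. When only the stronger peak of each overlap was kept, a setting added after seeing the data, 2897 peaks remained and the share within 1 kb was 13.5%, against 5.27% in random draws. It was 17.6% in replicate 1's own list, 18.8% in replicate 2's and 10.4% in the stronger 50% of peaks, against 3.18%, 3.01% and 2.9% in random draws.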

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

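Some peaks outside the lists used for the comparisons passed the same threshold. The test on repeats was set before its result was seen, and the comparison of groups of peaks for the spaced sequence after it.

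In the ranked conservative list 94 peaks passed the IDR threshold but were absent from the thresholded list, which names an additional source that the descriptions do not explain. On the 7 chromosomes there were 84, in 43 groups more than 20 kb apart, and 11 of them were stronger than the 500th conservative peak. The strongest lay in introns of cbt, a transcription factor gene (2L 480965 to 481221, pooled signal value 894), and Lk6, a kinase gene (3R 11760923 to 11761162, 877), and 96 bp from a TSS of Sin3A, a corepressor gene (2R 12592864 to 12593165, 729.8). By pooled value these would rank 35, 37 and 62 among the kept peaks. Pooled values cannot be set beside the replicate means given for the 20 strongest kept peaks. Further ones were in introns of jumu (701), Unc-115a (628) and the trithorax gene trx (430.5), and beside larp (579). Chromosome arm 3R held 54 of the 84 (64.3%), against 21.9% of the kept peaks (two-sided Fisher's exact p = 3.1e-16), and 44.0% of the 84 lay within 500 bp of a TSS. That p-value takes the 84 peaks as independent, though they fall in 43 groups, and the groups were not tested. The median signal value of the 84 peaks, 111, was close to the 107 of the kept peaks.

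Among technical explanations for the absence of these 84 peaks, repeated sequence was tested through overlap with annotated transposable elements, which 2.38% of them had (95% Wilson interval 0.655 to 8.27), against 1.46% of kept peaks (Fisher's exact p = 0.357). With 2 overlaps in 84 peaks this leaves repeats open as an explanation, and other kinds of repeat were not examined. That they are signal unlike that of kept peaks was tested with the spaced sequence described under the other observations. It occurred in 3.57% of them (3 of 84, 1.22 to 9.98), against 7.22% of kept peaks (Fisher's exact p = 0.28) and 0.891% of flanks of kept peaks. The bound set first, above the flanks, was met when peaks were counted singly. It took the peaks as independent, though they fall in 43 groups, and resampling the groups gave an interval of 0 to 8.22, which holds both values. Most kept peaks lack the sequence as well, so this explanation stays open. The additional source may be an exclusion list of regions prone to false signal. In that case the 84 peaks were removed on purpose and are no evidence of binding. No content of that source is given here, so this was not tested and stays open. The design gives no group that could set a biological explanation against these, and none was tested.

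The conservative list also held 11 peaks on contigs outside the 7 chromosomes, all on contigs assigned to the X without a position, with a median signal value of 104. Replicate 2's own list had 42 such peaks among 2233 and replicate 1's had 3 among 2081.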

How the results depend on the processing

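The settings that merge overlapping peaks, add back absent peaks or match lists on TSS number were chosen after seeing the data. No paired analysis was possible because the series has 1 group. Over all alternatives, 128 values answered a main comparison. Of these, 105 stayed on their side of the threshold, within their spread or, for counts, within a factor of 1.5. A further 22 moved and 1 fell short of the threshold. Of the other values, such as those of single gene lists, biotypes and chromosomes, 443 stayed the same in this sense. Another 27 fell short of the threshold, 6 passed it anew and 2 turned direction. The TSS share ranged from 30.9% to 53.5% and stayed above the sub-threshold share in each. Unknown depth limits all counts, since a peak absent from a list may lie under its detection limit, and 92.5% of the peaks of replicate 1 alone overlapped a ranked peak of replicate 2, against 71.3% of its sub-threshold peaks (64.2% with 50% reciprocal overlap, and 66.3% for replicate 2).

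With 50% reciprocal overlap the shared peaks were 66.2% (replicate 1) and 62.8% (replicate 2), the conservative peaks in the optimal list 89.7% and the reverse 75.6%. With summits within 100 bp the replicates shared 72.7% and 69.0%, and in the stronger 50% of each list 83.3% and 79.2%. The overlap rules count fewer pairs by construction. For the rest the cause was not tested. With flanks 1000 bp away 246 8-mers were more and 47 less frequent in centres, and 1 known site was more and 1 less frequent. The optimal list gave 1 more frequent site. Leaving out a replicate gave 1 to 2 more frequent and 2 to 4 less frequent sites. Lists above other genes numbered 1 rather than 2 with a TSS window of 250 bp, with TSS-matched lists, with a background of genes with a ranked peak, and with either replicate left out. The stronger 50% of peaks also gave 2 lists, but heat shock proteins in place of signalling. The signal difference at TSSs was 0.05 (log2) with a window of 250 bp. With a window of 1000 bp the snoRNA ratio turned to 1.03 and the intron share to 33.2%, below its background.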

Other observations

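All tests of an explanation in this part were chosen, or given their present form, after related results were seen.

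A minority of strong peaks carried a spaced sequence, GNGGNCANNNNAATAG, in which N is any base. It was put together from 8-mers and from alignments of the strongest peaks after several patterns and starting points had been tried, and starts on all peaks of chromosome 2 had drifted to A/T repeats. The shares in the same peaks are therefore optimistic, and the sequence is a hypothesis about these data. With at least 9 of its 10 fixed bases it occurred within 50 bp of the summit at 82 of the 500 strongest peaks (16.4%, 95% Wilson interval 13.4 to 19.9), against 1.2% of their flanks. The share was 9.4% in the next 1000 peaks and 3.1% in the 1643 weakest, where the flanks had 0.8% and 0.852%. Over all conservative peaks it was in 10.4% of intronic ones (8.83 to 12.1), 6.89% of intergenic ones (4.84 to 9.72) and 3.87% of TSS peaks (2.95 to 5.06), classes that were not tested against each other. Both replicates' own lists had it, with 9.0% and 9.22%, and among 91996 sub-threshold peaks it was in 0.675%.

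In the genome the full sequence occurred 463 times on the 7 chromosomes, and 122 of these places lay in a conservative peak (26.3%, 22.5 to 30.5), while such peaks cover 0.688% of the bases. No test is given for this, since the sequence was chosen from the same peaks. Within 500 bp of a TSS 26 of 58 occurrences were in a peak (44.8%, 32.7 to 57.5), and elsewhere 96 of 405 (23.7%, 19.8 to 28.1). A further 140 occurrences lay in sub-threshold peaks alone.

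Fitting a pattern to the peaks it was seen in was tested by taking the leading 8-mer with at least 2 G or C bases from 1 set of chromosomes, fitting a matrix there and searching the other set. From chromosomes 3, 4 and X the start was ATAATAGC and the matrix read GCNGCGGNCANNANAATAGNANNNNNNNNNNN. It found 5.34% of centres and 0.534% of flanks on chromosome 2 (exact McNemar p = 2.7e-12), which argues against such fitting as the whole account. In the other direction the sequence was not recovered: from TGAAGAAA the matrix drifted to A-rich letters and found 2.03% and 1.14% (exact McNemar p = 0.0273). Earlier fits, started by hand from AATAG followed by A or C and then A, a start picked on all chromosomes, had found 7.43% and 1.29% from chromosome 2 and 5.69% and 0.712% from the others. A/T-rich composition of summits was tested by shuffling the positions of the matrices: 0 of 1000 shuffles reached the difference of 4.8 percentage points of the matrix from chromosomes 3, 4 and X, the highest being 0.801, which argues against composition as the whole account. Of the chromosome 2 matrix 478 of 1000 did, but it holds 4 of the 10 fixed bases and does not bear on the sequence. The rule to read only matrices that hold at least 9 was set after both counts were seen, and the evidence rests on a single direction. An earlier test that rearranged the letters of the sequence was dropped because it ran on the peaks the sequence was chosen from. The sequence may mark a site of the tagged protein or of a partner. This is a hypothesis found and tested on the same data, and no biological explanation was tested.

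The high share of ribosomal protein promoters was weighed against 3 explanations. Signal at housekeeping genes in general would raise other such lists, but of the 268 genes of the mitochondrial ribosome, oxidative phosphorylation, the proteasome, and basal transcription and Mediator, 11.2% were bound (95% Wilson interval 7.95 to 15.5). This lies below the lower bound of 37.9% for ribosomal protein genes, and these 4 lists were picked after their shares were seen. The number of TSSs per gene was excluded as the whole account by matched random lists (permutation p = 2.0e-04, the smallest the draws can give). Sites with the spaced sequence do not account for the excess either: 0% of the 44 peaks carried it, with an upper bound of 8.03%, while the excess over other genes is 79.5% of the bound genes. An earlier bound, the 4.0% of other TSS peaks, did not separate them (Fisher's exact p = 0.411), and the present one was set after that. Transcript levels were not analysed here, so signal that follows very high transcription remains a candidate explanation, and no biological explanation was tested.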
